A study of Homo sapiens with 36 samples.

How the data were processed

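RNA was measured in 36 libraries of the human ovarian cancer cell lines HEY1 and SKOV3. Per the labels' protocols, cells carrying a construct named IcNFATc4 or ILUC received 100 ng/mL doxycycline, the drug that switches inducible constructs on, for 24, 48 or 96 h. Also per the labels' protocols, RNA was column-purified and checked for integrity, polyA-selected libraries were made, and paired ends were read on an Illumina NextSeq. Each of the 12 groups (2 lines, 2 arms, 3 times) holds 3 libraries, numbered 1 to 3 in the titles. The labels do not say that these came from separate cultures, so p-values measure only the spread between these samples, which may be technical.

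The authors deposited 1 table of 48162 genes with 4 kinds of values, per the file headers. The whole-number counts per gene and library deposited by the authors were used for all tests here. FPKM values per library and FPKM group means deposited by the authors were used only to find which libraries each of their comparisons held. The authors' log2 fold changes and p-values for 6 comparisons, deposited in the same table, are quoted only where "the authors' deposited table" is named, and their test is not given in the sources used here. The submitters' processing notes name CASAVA and the build mm10, a mouse assembly. The gene identifiers are human Ensembl identifiers. The aligner, the counting tool, whether counting used strand, and the human annotation are not given in the sources used here. Of 45342 genes matched by identifier to GENCODE 29, 45292 lie on the same chromosome but 261 have the same start and end, so the coordinates are not those of GRCh38. Coordinates are printed as the authors' table gives them, 1-based, on a build that is not given in the sources used here. Of the gene names, 29 had turned into dates, and 28 were restored from the identifier. A second deposited table, a re-sorted copy with averaged fold changes, was not used here.

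The sample codes are HN, HP, SN and SL. Titles and genotype tags both assign HN to ILUC and HP to IcNFATc4. For SKOV3 the titles assign SL to IcNFATc4 and SN to ILUC, and the genotype tags assign them the other way round. NFATC4 counts were high in every HN and SN library and low in every HP and SL library, so they go against both labels in HEY1 and against the titles in SKOV3. Libraries are therefore named by their codes. The authors' FPKM means of groups HT, HC, ST and SC equal those of HN, HP, SN and SL for 100% of genes. Their comparisons set HT against HC and ST against SC. The design, fixed before the data were examined, took the HEY1 effect as IcNFATc4 minus ILUC by the labels, which is HP minus HN. All HEY1 effects are printed here as HN minus HP, and all SKOV3 effects as SN minus SL. The difference between lines was fixed by the genotype tags, which in printed signs is the SKOV3 effect plus the HEY1 effect, and the reading by titles, the SKOV3 effect minus the HEY1 effect, was its alternative, fixed at the same time.

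Counts were analysed in R 4.3.3 with edgeR 4.0.16. Genes with low counts were removed with filterByExpr (minimum count 10), library sizes were re-summed, TMM factors were computed, and the quasi-likelihood test (glmQLFit and glmQLFTest) was run on a model with 1 mean per group. The 18 libraries of a line entered 1 fit (14890 genes tested in HEY1, 16350 in SKOV3, 12 residual degrees of freedom each), and all 36 entered the fit for the difference between lines (17524 genes, 24 residual degrees of freedom). The common biological coefficient of variation was 0.107 in HEY1, 0.149 in SKOV3 and 0.131 over both. A gene passed at a Benjamini-Hochberg adjusted p under 0.05. All adjusted p-values printed for genes come from edgeR's quasi-likelihood test, and all standard errors (SE) are the log2 fold change divided by the square root of its F statistic. Comparisons were the arms at 24, 48 and 96 h and as the mean of these 3 effects, each arm at 96 h against 24 h, and the change of the arm effect from 24 to 96 h. Levels are CPM, counts scaled to library size with TMM, as mean ± SD.

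Total counts were 11749459 to 18798662 per library (median 15057913). Where an arm had 0 counts, the fold is a lower bound computed against a floor of 3 counts over the whole arm. Where it had 1 to 3 counts, the fold is a ratio of scaled counts with a 95% counting interval. Intervals and floors cover counting error only. Fitted log2 fold changes of genes close to 0 counts in an arm depend on the prior count. Some genes had groups without counts on both sides of a contrast, so that no fold can be estimated. There were 14 in each mean effect, 44 and 81 in the HEY1 and SKOV3 changes of the arm effect, and 1010 and 1054 in the differences between lines by genotype tag and by title. None of them passed. Between replicates, chi-square per degree of freedom of the counts lay between 4.4 and 33.6 in all 36 pairs, so none of these pairs of libraries from 1 group was a repeat.

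Gene lists, 32 in all, were fixed before the data were examined. They cover NFAT and calcineurin, S phase, G2/M, CDK inhibitors and cell cycle exit, G1 cyclins and E2F, activin and follistatin, the TGF-beta response, p53 targets, MYC targets and ribosome biogenesis, cytosolic ribosomal proteins, mitochondrially encoded mRNAs, nuclear respiratory chain subunits, glycolysis and hypoxia, cholesterol synthesis, the unfolded protein response, the integrated stress response, interferon, NF-kB and cytokines, immediate early genes, mesenchymal genes, epithelial genes, extracellular matrix, ovarian cancer stem cell markers, drug transport and resistance, lysosome and autophagy, WNT targets, YAP targets, histones, and markers of immune, endothelial, fibroblast and neuronal cells. Lists were tested with camera (limma 3.58.1) on log2 CPM with a prior count of 2 and a preset correlation of 0.01, adjusted over 256 tests of arm contrasts and 192 tests of time contrasts. An alternative fixed at the same time estimated the correlation between members. Under it no list test passed in either family, against 53 and 68 with the preset value, and 16 and 22 had an unadjusted p under 0.05. Counts of list members that passed are given over all genes tested and adjusted over the list alone.

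Named genes follow a rule fixed before the data were examined. For mean effects it takes the 12 largest in each direction with a mean log2 CPM of at least 1 and the same sign at the 3 times. For single times, times within an arm and interactions it takes the 4 largest in each direction. For each list it takes up to 4 members with the smallest adjusted p and up to 2 that did not pass. NFATC4, FST and the members of the NFAT and activin lists could always be named. Genes chosen otherwise are marked as chosen after their values were seen. Some genes that the rule takes are not reported here.

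Alternatives were size factors of DESeq2 1.42.0 in edgeR (RLE), no filter on low counts, the DESeq2 Wald test, a replicate block, only the compared groups in the fit, each library left out in turn, the title reading of the SKOV3 labels, and a 2-fold threshold for the overlap between lines. Another, added after the data were seen, leaves out the SKOV3 24 h libraries numbered 2 of both arms. Against TMM scaling, dividing by total counts alone would shift the median of all genes to -0.10 for the HEY1 arm effect at 96 h, -0.11 for its change from 24 h and 0.12 for SN at 96 h against 24 h. Changes are relative to TMM.

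Replicate numbers were checked for pairing by the correlation of deviations from the group means between same-numbered libraries of the 2 arms. Every pair was over 0.1 only for SKOV3 at 96 h (0.153, 0.103 and 0.28). With the replicate number as a block, 7674 genes passed there in place of 7071.

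The edgeR step was tested on simulated counts with 200 changed genes. For the mean effect it recovered 71.6%, 95.5% and 92.4% of genes changed 1.5-fold, 2-fold and 4-fold in HEY1 and 58.2%, 82.1% and 97% in SKOV3. At 24 h it recovered 43.3%, 68.7% and 84.8% in HEY1 and 25.4%, 62.7% and 83.3% in SKOV3. Unchanged genes were called in at most 0.068% of cases. Far more genes passed in the data, so these rates may not carry over. Other steps used Python 3.11.15, pandas 2.3.3, numpy 2.4.6, scipy 1.17.1 and matplotlib 3.10.9.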

Results

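The series compares ovarian cancer cells that carry constructs named IcNFATc4 or ILUC, and its title names quiescent cells, chemotherapy and follistatin. NFATC4 is a transcription factor that calcineurin, a phosphatase switched on by calcium, sends to the nucleus. Follistatin, the product of FST, is a secreted protein that binds and neutralises activins. The human ovarian cancer lines HEY1 and SKOV3 were given doxycycline for 24, 48 or 96 h in 2 arms, with 3 libraries per group. RNA was counted per gene. The libraries labelled ILUC in HEY1 (HN) held the high NFATC4 counts, and those labelled IcNFATc4 (HP) the low ones. In SKOV3 the labels disagree with each other: SN is ILUC by title and IcNFATc4 by genotype tag, and SL is the reverse. Arms are therefore named by code, and every effect is HN minus HP or SN minus SL, so that a positive value means more RNA in the arm with more NFATC4 RNA. Log2 fold changes are given ± SE and come from edgeR's quasi-likelihood test, with Benjamini-Hochberg adjusted p. Where the adjusted p of a gene is not printed, it was under 0.001. Counts of list members that passed are over all genes tested. Those adjusted over the list alone follow in brackets where they differ, and are the same where no bracket is given.

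NFATC4, its feedback inhibitor RCAN1 and FST all stood far higher in HN than in HP and in SN than in SL. In HEY1, NFATC4 (ENSG00000100968, chr14:24834879-24848810) was at 639.5 ± 24.1, 997 ± 99.6 and 1352 ± 22.1 CPM (mean ± SD, n=3) at 24, 48 and 96 h in HN and at 5.78 ± 2.42, 6.75 ± 2.39 and 9.75 ± 2.73 in HP. The mean effect was log2 7.04 ± 0.13, adjusted p = 7.07e-22. In SKOV3 the SN libraries had 2526 ± 377, 2834 ± 365 and 3030.0 ± 439.8 CPM, and the SL libraries had 0 to 2 counts each. The mean effect there was log2 15.32 ± 0.20, adjusted p = 6.71e-22. RCAN1 (ENSG00000159200, chr21:35885440-35987441), a calcineurin inhibitor and classical NFAT target, was at 3084 ± 359, 4762 ± 128 and 5097 ± 44.5 CPM in HN and 27.2 ± 1.24, 25.7 ± 0.652 and 24.8 ± 2.13 in HP (log2 7.35 ± 0.06, adjusted p = 1.36e-28). Its SKOV3 levels were 6434 ± 1098, 6532 ± 491 and 6313 ± 972 CPM in SN and 34.0 ± 3.92, 31.4 ± 0.965 and 32.1 ± 2.83 in SL (log2 7.63 ± 0.10, adjusted p = 6.71e-22). FST (ENSG00000134363, chr5:52776239-52782964) reached 522 ± 20.7, 880.0 ± 73.8 and 1026 ± 68.2 CPM in HN against 0.955 ± 0.576, 1.16 ± 0.386 and 2.14 ± 0.0996 in HP (log2 9.17 ± 0.10, adjusted p = 9.97e-26). In SKOV3, FST was at 6.68 ± 4.54, 33.6 ± 15.9 and 26.5 ± 9.78 CPM in SN against 0.204, 0.174 and 0.117 in SL (log2 6.74 ± 0.40, adjusted p = 1.83e-11).

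**Figure D1:**
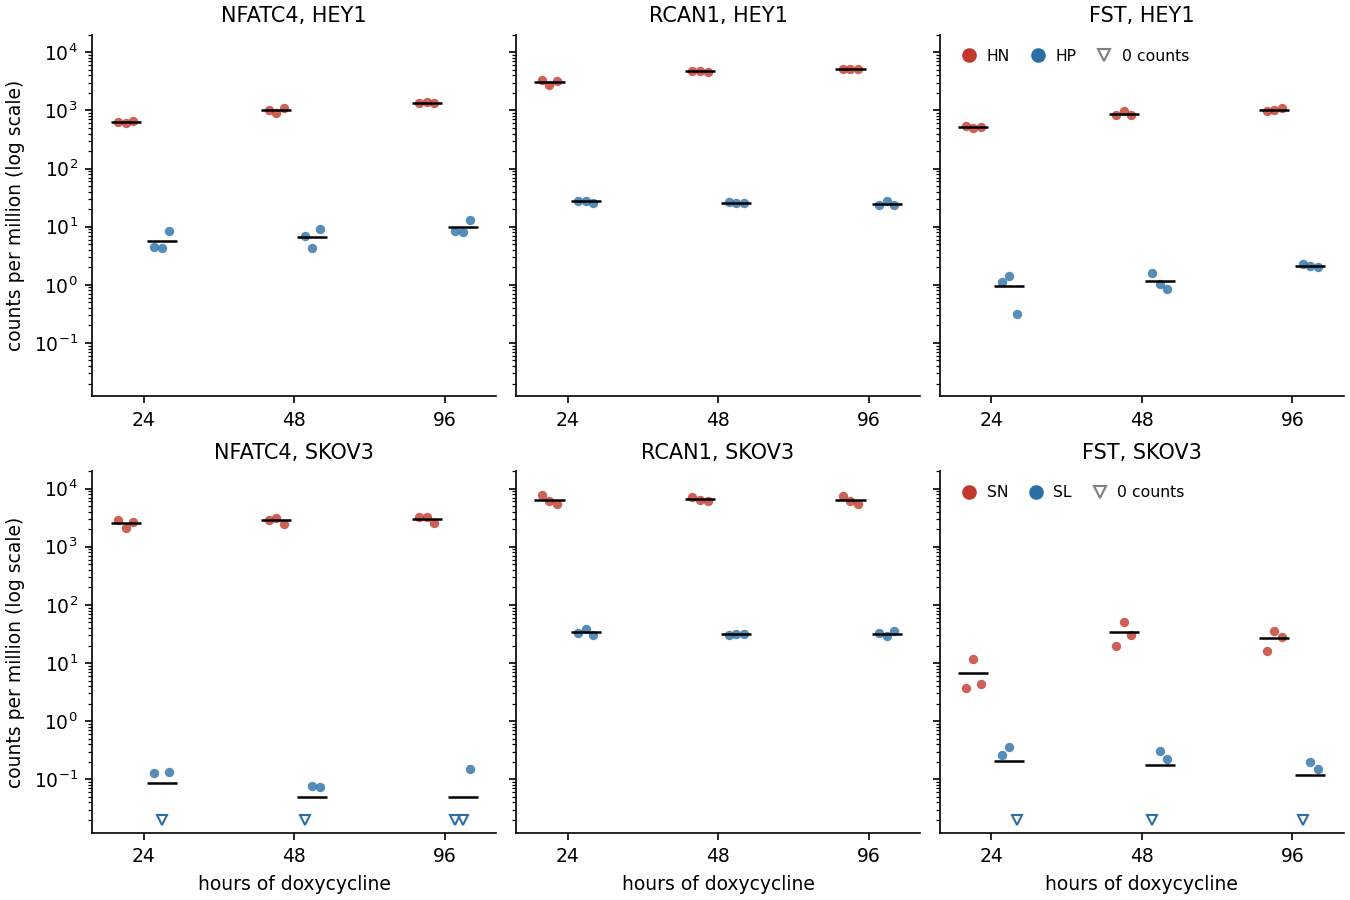
CPM (scaled counts) of NFATC4, RCAN1 and FST in every library of HEY1 (top) and SKOV3 (bottom) at 24, 48 and 96 h of doxycycline, on a log scale. Points are libraries, bars are group means of 3 libraries, and open triangles are libraries with 0 counts.

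The arms parted along the main axis of variation in both lines, and the HN libraries moved further from HP with time. The first principal component of log2 CPM held 63% of the variance in HEY1 and 56% in SKOV3. HP libraries stayed between -52.3 and -43.8 on it, and HN libraries lay at 2.6 to 10.5 at 24 h, 49.8 to 55.5 at 48 h and 87.9 to 90.5 at 96 h. SL libraries lay between -62 and -54.7, and SN libraries at 26.1 to 36 at 24 h, 57.4 to 66.8 at 48 h and 77.7 to 79.5 at 96 h. On the second component the 24 h libraries numbered 1, 2 and 3 lay at -29.6, -41.8 and 1.3 in SL and at -33.4, -62.5 and -15.7 in SN.

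**Figure D2:**
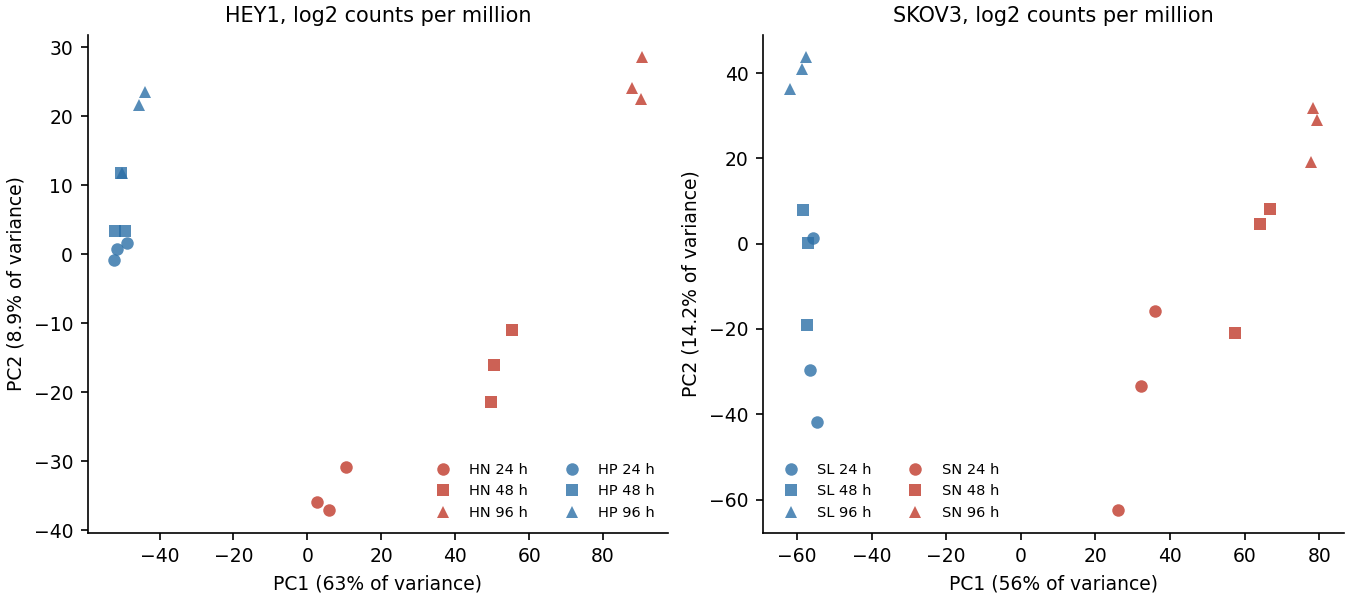
First and second principal components of log2 CPM, 18 libraries per line. Colours are the arms (red HN and SN, blue HP and SL) and marker shapes are the times.

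Most of the genes with the largest differences upward in HN had few or no counts in HP. COL3A1, which encodes type III collagen (ENSG00000168542, chr2:189839046-189877472), was at 11.2 ± 3.77, 116 ± 18.6 and 1526 ± 83.2 CPM at 24, 48 and 96 h in HN (n=3) and at 0.0466, 0.0240 and 0.108 in HP (log2 11.09 ± 0.22, adjusted p = 1.88e-21). POSTN, the matrix protein periostin (ENSG00000133110, chr13:38136720-38172981), reached 0.877, 9.74 and 43.0 CPM in HN with no counts in HP (at least 776-fold, adjusted p = 1.52e-10). CNN1, calponin of smooth muscle (log2 8.75 ± 0.17, adjusted p = 2.55e-21), and ANO1, a calcium-activated chloride channel (log2 8.54 ± 0.10, adjusted p = 2.88e-25), were also higher. The nicotinic receptor subunit CHRNA6 had 7269 counts in HN and 0 in HP (at least 2300-fold, adjusted p = 2.27e-16). TMPRSS15, the protease that activates trypsinogen (log2 10.56 ± 0.22, adjusted p = 1.53e-19), RUFY4 (at least 500-fold, adjusted p = 2.39e-13) and LCK, a tyrosine kinase best known from T cells (1340-fold, interval 241 to 53000, adjusted p = 4.15e-15), were in the same group. So were REM1, a small GTPase (at least 396-fold, adjusted p = 2.96e-13), and DEFB124 (at least 220-fold, adjusted p = 1.58e-11). DEFB124 overlaps REM1 in position, and without strand the reads of the 2 cannot be told apart.

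Among the genes lower in HN were the inflammatory cytokines IL1A and IL1B and the growth factor FGF5. IL1B (ENSG00000125538, chr2:113587328-113594480) was at 2.91, 1.58 and 1.2 CPM in HN and 14.4, 19 and 42.9 in HP at 24, 48 and 96 h (log2 -3.69 ± 0.18, adjusted p = 2.82e-14). IL1A (ENSG00000115008, chr2:113531492-113542167) was at 16.6, 6.99 and 5.30 CPM in HN and 53.4, 89.5 and 142 in HP (log2 -3.36 ± 0.13, adjusted p = 4.16e-16). FGF5 (ENSG00000138675, chr4:81187753-81257834) had 15.9, 7.02 and 6.11 CPM in HN and 108, 87.7 and 89.8 in HP (log2 -3.43 ± 0.17, adjusted p = 3.45e-14). NOX4, an oxidase that makes reactive oxygen (log2 -3.26 ± 0.21, adjusted p = 5.85e-12), SPNS2, a transporter of sphingosine-1-phosphate (log2 -3.35 ± 0.11, adjusted p = 4.14e-17), TMEM158 (log2 -3.41 ± 0.15, adjusted p = 4.83e-15) and AJAP1 (log2 -3.26 ± 0.13, adjusted p = 4.62e-16) were lower too. Also lower were the zinc finger gene ZNF91 (log2 -5.70 ± 0.31, adjusted p = 2.20e-13), which had the largest difference, its relative ZNF724P (log2 -4.41 ± 0.25, adjusted p = 5.45e-13), RP11-245M24.1 (log2 -4.10 ± 0.22, adjusted p = 1.52e-13), MYH16 (log2 -3.43 ± 0.15, adjusted p = 5.00e-15) and C6orf141 (log2 -3.29 ± 0.25, adjusted p = 9.97e-11). ZNF91 and ZNF724P are close in sequence, so reads of 1 may count for the other, and SPNS2 overlaps MYBBP1A. In the mean effect of HEY1, 8995 of 14890 genes passed edgeR's test, 4478 higher and 4517 lower in HN, and 2073 of them at least 2-fold.

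In the HEY1 mean effect, lists of ribosome, G1, S phase and stress response genes passed downward in HN, and matrix, activin, glycolysis and histone lists upward, none with an estimated correlation. The ribosome biogenesis list had 0 higher and 33 lower of 36, median log2 -0.67, adjusted p = 6.00e-12 (0.672 with estimated correlation). Its members include ODC1, the first enzyme of polyamine synthesis (log2 -1.22 ± 0.05), and the nucleolar gene NOLC1 (log2 -1.02 ± 0.05), while HSPE1 (log2 -0.11 ± 0.14, adjusted p = 0.524) did not pass. The G1 cyclin and E2F list had 1 higher and 12 lower of 17, median log2 -0.28, adjusted p = 0.00468 (0.672 with estimated correlation). MYC, the growth-promoting transcription factor, was at 78.1, 67.8 and 40.5 CPM in HN and 192, 255 and 238 in HP (log2 -1.92 ± 0.08), and the cyclin CCND2 was lower (log2 -2.85 ± 0.18). S phase genes had 1 higher and 23 lower of 42, median log2 -0.16, adjusted p = 0.00767 (0.83 with estimated correlation), among them the replication clamp PCNA (log2 -0.78 ± 0.06). Cytosolic ribosomal proteins had 3 higher and 25 lower of 54, median log2 -0.10, adjusted p = 0.0208 (0.846 with estimated correlation), with RPL14 at log2 -0.66 ± 0.04. The integrated stress response, a programme that follows amino acid shortage and other stress, had 6 higher and 15 lower of 28, median log2 -0.28, adjusted p = 0.0261 (0.768 with estimated correlation). The amino acid transporter SLC7A5 (log2 -1.46 ± 0.07) was among its members.

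Collagens and other matrix genes had 19 higher and 11 lower of 36, median log2 0.36, adjusted p = 0.0227 (0.808 with estimated correlation). COL12A1 (log2 4.33 ± 0.06) and COL5A1 (log2 3.69 ± 0.06) were higher. Glycolysis and hypoxia genes had 22 higher and 5 lower of 33 (22 and 6 adjusted over the list alone), median log2 0.32, adjusted p = 0.00598 (0.817 with estimated correlation). P4HA1, a collagen prolyl hydroxylase that responds to hypoxia, was at 45.7, 105 and 175 CPM in HN and 37.4, 36.5 and 39.0 in HP at 24, 48 and 96 h (log2 1.32 ± 0.07). The vasodilator peptide ADM, also a hypoxia gene, was lower (log2 -2.12 ± 0.12). Histone genes had 10 higher and 2 lower of 14, median log2 0.90, adjusted p = 0.0181 (0.672 with estimated correlation). HIST1H2BK (log2 1.39 ± 0.08) was higher, as was H1F0, a linker histone of resting cells that is not tied to replication (log2 0.71 ± 0.05).

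Apart from activin and follistatin genes (adjusted p = 0.00834, 0.672 with an estimated correlation), the other lists did not pass in the HEY1 mean effect. CDK inhibitors and genes of cell cycle exit had 18 higher and 8 lower of 35, median log2 0.31, adjusted p = 0.186, and GAS1, a gene of growth-arrested cells, was higher (log2 4.76 ± 0.18). G2/M genes had 11 higher and 13 lower of 52 (6 and 11 adjusted over the list alone), median log2 -0.02, adjusted p = 0.797. TGF-beta genes had 10 higher and 8 lower of 20 (11 and 8 adjusted over the list alone), median log2 0.16, adjusted p = 0.266, with the ligand TGFB2 higher (log2 3.15 ± 0.08). NF-kB and cytokine genes had 8 higher and 16 lower of 24, median log2 -0.61, adjusted p = 0.109. Interferon genes had 14 higher and 7 lower of 29, median log2 0.17, adjusted p = 0.245. The unfolded protein response had 12 higher and 4 lower of 20, median log2 0.26, adjusted p = 0.196. For p53 targets there were 7 higher and 9 lower of 25, median log2 0.02, adjusted p = 0.991, where the mean of members (-0.05) has the opposite sign to the median. Mesenchymal genes had 13 higher and 7 lower of 22, median log2 0.37, adjusted p = 0.223. Epithelial genes had 4 higher and 5 lower of 11, median log2 0.07, adjusted p = 0.566, with a mean of -0.44. Cholesterol synthesis had 5 higher and 11 lower of 23, median log2 -0.12, adjusted p = 0.245. Mitochondrial mRNAs had 1 higher and 2 lower of 13 (0 and 2 adjusted over the list alone), median log2 -0.05, adjusted p = 0.774. Nuclear respiratory chain subunits had 11 higher and 9 lower of 41, median log2 0.03, adjusted p = 0.912.

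The HEY1 arms grew apart over time. At 24 h, TMPRSS15 (2510-fold, interval 451 to 99300), CNN1 (694-fold, interval 192 to 5730) and CHRNA6 (at least 44.6-fold) led the genes higher in HN with FST (log2 9.04 ± 0.19). ZNF91 (log2 -4.83 ± 0.47) and SIRPB1 (log2 -3.51 ± 0.57) were among those lower. At 48 h CHRNA6 (at least 650-fold), TMPRSS15 (at least 655-fold), COL3A1 (5080-fold, interval 912 to 201000) and MRGPRF (at least 227-fold) led. At 96 h COL3A1 (log2 13.73 ± 0.32), CHRNA6 (at least 1750-fold), POSTN (at least 688-fold) and the alarmin cytokine IL33 (at least 469-fold) led. ZNF91 (72.3-fold, interval 24.7 to 350), RP11-245M24.1 (71.6-fold, interval 24.5 to 347), NOX4 (log2 -5.85 ± 0.44) and KIAA1755 (log2 -5.51 ± 0.44) were lowest. Genes passing numbered 3436, 6160 and 8412 at 24, 48 and 96 h, of which 886, 2041 and 3270 were at least 2-fold. Of those passing at 24 h, 2773 also passed in the same direction at 96 h and 117 in the opposite one.

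Most members of the S phase and G2/M lists were lower in HN than in HP at 96 h. S phase genes had 0 higher and 36 lower of 42 (0 and 37 adjusted over the list alone), median log2 -0.54, adjusted p = 5.60e-08 (0.808 with estimated correlation). UHRF1, which keeps up DNA methylation at replication, had log2 -1.33 ± 0.11, and the ribonucleotide reductase subunit RRM2 had log2 -1.01 ± 0.09. G2/M genes had 2 higher and 32 lower of 52 (2 and 33 adjusted over the list alone), median log2 -0.35, adjusted p = 0.0028 (0.808 with estimated correlation), with the mitotic activator CDC20 at log2 -0.89 ± 0.09. At 24 h the same G2/M list had 8 higher and 1 lower of 52 (6 and 1 adjusted over the list alone), median log2 0.16, adjusted p = 0.0173 (0.817 with estimated correlation). Histone genes at 96 h had 10 higher and 0 lower of 14, median log2 1.56, adjusted p = 0.00479 (0.616 with estimated correlation). Ribosome biogenesis genes had 0 higher and 25 lower of 36 (0 and 28 adjusted over the list alone), median log2 -0.37, adjusted p = 9.82e-09 (0.768 with estimated correlation) already at 24 h. At 96 h they had 0 higher and 34 lower of 36, median log2 -0.98, adjusted p = 6.00e-12 (0.672 with estimated correlation). Glycolysis and hypoxia genes at 96 h had 22 higher and 3 lower of 33, median log2 0.69, adjusted p = 0.000257 (0.808 with estimated correlation), with P4HA1 at log2 2.16 ± 0.12 and the mitophagy gene BNIP3 at log2 1.87 ± 0.13. G1 cyclin (lower), activin and matrix lists (higher) also passed at each time, stress response genes (lower) at 48 and 96 h, ribosome biogenesis (lower) and glycolysis (higher) at 48 h and ribosomal proteins (lower) at 96 h.

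In SKOV3 too, most of the genes with the largest differences upward in SN had few or no counts in SL. SFRP4, a secreted WNT antagonist (ENSG00000106483, chr7:37945543-38065297), was at 11.8, 69.2 and 96.6 CPM at 24, 48 and 96 h in SN (log2 9.96 ± 0.55, adjusted p = 2.80e-11), though it overlaps EPDR1. POSTN was at 5.26, 33.4 and 47.9 CPM (1270-fold, interval 435 to 6170, adjusted p = 8.66e-12), and LCK at 32.1, 124 and 147 (log2 9.22 ± 0.26, adjusted p = 2.65e-16). KRT33B, a hair keratin with close relatives (log2 10.83 ± 0.49, adjusted p = 1.78e-12), CNN1 (log2 9.44 ± 0.36, adjusted p = 2.36e-14), CHRNA6 (1580-fold, interval 283 to 62300, adjusted p = 8.82e-14) and RUFY4 (at least 486-fold, adjusted p = 3.34e-11) were higher as well. MYCT1 (log2 10.12 ± 0.41, adjusted p = 4.67e-13), the collagen-binding proteoglycan FMOD (log2 8.98 ± 0.65, adjusted p = 1.41e-09), DMRTB1 (at least 534-fold, adjusted p = 1.60e-06) and RP11-180C1.1 (at least 190-fold, adjusted p = 2.27e-10) complete the 12 largest with NFATC4.

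Lower in SN were the cell adhesion gene CDH6 (ENSG00000113361, chr5:31193857-31329253), at 3.19, 0.261 and 0.129 CPM in SN and 169, 209.8 and 302 in SL (log2 -8.79 ± 0.21, adjusted p = 2.59e-17), and the matrix proteoglycan BGN, at 0.723, 0.788 and 0.465 and 196, 169 and 398 (log2 -8.52 ± 0.18, adjusted p = 3.50e-18). H19, an imprinted non-coding RNA (ENSG00000130600, chr11:2016406-2022700), was at 53.3, 15 and 2.10 CPM in SN and 969, 1309 and 2954 in SL (log2 -7.03 ± 0.19, adjusted p = 2.23e-16). KRT14, a keratin of basal epithelium (log2 -6.98 ± 0.28, adjusted p = 5.45e-14), HHIP, which binds hedgehog ligands (log2 -6.85 ± 0.29, adjusted p = 9.04e-14), and BIRC7, an inhibitor of apoptosis (log2 -7.57 ± 0.34, adjusted p = 1.43e-12), were lower. So were AMTN (log2 -8.33 ± 0.33, adjusted p = 3.61e-13), NTNG1 (log2 -7.71 ± 0.40, adjusted p = 7.53e-11), MAL2 (195-fold, interval 66.6 to 944, adjusted p = 8.62e-11) and FAM5C (at least 195-fold, adjusted p = 4.84e-10). The cancer-testis antigens MAGEA11 (log2 -8.23 ± 0.25, adjusted p = 7.07e-16) and GAGE1 (305-fold, interval 84.4 to 2520, adjusted p = 4.11e-11) belong to families of near-identical genes whose reads may be shared. BGN overlaps HAUS7 and HHIP overlaps an antisense transcript. In the SKOV3 mean effect, 8991 of 16350 genes passed edgeR's test, 4613 higher and 4378 lower in SN, and 2445 of them at least 2-fold.

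The lists that passed in the SKOV3 mean effect pointed down in SN, and none passed with an estimated correlation. G1 cyclins and E2F genes had 1 higher and 11 lower of 15, median log2 -0.39, adjusted p = 0.0199 (0.817 with estimated correlation). Cyclin D1, encoded by CCND1, was at 94.3, 30.4 and 20.3 CPM in SN and 593, 346 and 221 in SL (log2 -3.20 ± 0.35). S phase genes had 2 higher and 19 lower of 42, median log2 -0.21, adjusted p = 0.0199 (0.846 with estimated correlation), with UHRF1 at log2 -1.63 ± 0.12. G2/M genes had 4 higher and 25 lower of 52, median log2 -0.24, adjusted p = 0.0277 (0.862 with estimated correlation). TACC3, a spindle protein, was lower (log2 -1.12 ± 0.12) and GAS2L3, a cytoskeletal linker, higher (log2 1.59 ± 0.09). Interferon genes had 3 higher and 17 lower of 29, median log2 -0.56, adjusted p = 0.0143 (0.817 with estimated correlation). OAS3, an antiviral enzyme, was at 17.3, 12 and 8.43 CPM in SN and 30.8, 30.2 and 43.5 in SL (log2 -1.51 ± 0.09), and the ubiquitin-like ISG15 was lower (log2 -1.27 ± 0.11).

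No other list passed in the SKOV3 mean effect. TGF-beta genes had 7 higher and 12 lower of 21, median log2 -0.41, adjusted p = 0.0727, with the AP-1 member JUNB lower (log2 -2.73 ± 0.09). The unfolded protein response had 12 higher and 2 lower of 20 (13 and 3 adjusted over the list alone), median log2 0.23, adjusted p = 0.0969, with its regulator XBP1 higher (log2 0.76 ± 0.06). Ribosome biogenesis had 2 higher and 8 lower of 36 (1 and 8 adjusted over the list alone), median log2 -0.05, adjusted p = 0.388. Cytosolic ribosomal proteins had 4 higher and 16 lower of 54 (4 and 14 adjusted over the list alone), median log2 -0.07, adjusted p = 0.186. Cholesterol synthesis had 2 higher and 10 lower of 23, median log2 -0.24, adjusted p = 0.119. Matrix genes had 10 higher and 17 lower of 36, median log2 -0.24, adjusted p = 0.175, and VCAN was lower (log2 -3.26 ± 0.13). Mesenchymal genes had 7 higher and 10 lower of 20, median log2 -0.44, adjusted p = 0.322, with a mean of 0.12 where the median is negative. MMP2, a gelatinase, was lower (log2 -3.78 ± 0.11), and LOX, which cross-links collagen, higher (log2 4.73 ± 0.17). Epithelial genes had 7 higher and 10 lower of 20 (7 and 11 adjusted over the list alone), median log2 -0.66, adjusted p = 0.178, including the tight junction gene CLDN4 (log2 -2.72 ± 0.20).

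NF-kB and cytokine genes had 14 higher and 5 lower of 24, median log2 0.47, adjusted p = 0.155, with the chemokine CCL2 higher (log2 8.27 ± 0.50). Stress response genes had 13 higher and 5 lower of 28 (14 and 5 adjusted over the list alone), median log2 0.26, adjusted p = 0.266, with ATF3 at 7.49, 18.1 and 18.3 CPM in SN and 3.87, 3.84 and 3.50 in SL (log2 1.86 ± 0.11). CDK inhibitors and cell cycle exit genes had 6 higher and 14 lower of 34 (7 and 15 adjusted over the list alone), median log2 -0.20, adjusted p = 0.269. Targets of p53 had 10 higher and 6 lower of 24, median log2 0.16, adjusted p = 0.631. Glycolysis and hypoxia genes had 13 higher and 13 lower of 32, median log2 0.10, adjusted p = 0.588. Histones had 5 higher and 2 lower of 13, median log2 0.48, adjusted p = 0.311. Mitochondrial mRNAs had 4 higher and 0 lower of 13, median log2 0.14, adjusted p = 0.189. Nuclear respiratory chain subunits had 5 higher and 9 lower of 41, median log2 -0.07, adjusted p = 0.566.

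More genes differed between SN and SL at each later time. At 24 h MYCT1 (1180-fold, interval 212 to 46600), KRT33B (714-fold, interval 244 to 3460) and POSTN (at least 78.5-fold) led upward after NFATC4 (log2 14.65 ± 0.33), and GAGE1 (at least 76.4-fold) and MAL2 (at least 53.5-fold) downward. At 48 h FMOD (at least 517-fold) and CYP11A1, the first enzyme of steroid hormone synthesis (at least 317-fold), were among the highest and CDH6 (log2 -9.52 ± 0.38) among the lowest. At 96 h SFRP4 (at least 1290-fold), MYCT1 (at least 403-fold) and DMRTB1 (at least 390-fold) led after NFATC4 (59900-fold, interval 16600 to 495000). AMTN (at least 661-fold), CDH6 (log2 -11.13 ± 0.42), BIRC7 (at least 240-fold) and H19 (log2 -10.45 ± 0.39) were lowest. Genes passing numbered 4025, 5808 and 7071 at 24, 48 and 96 h (1611, 2409 and 2977 at least 2-fold). Without the 24 h libraries numbered 2 the counts were 3113, 6283 and 7528.

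S phase genes at 24 h had 0 higher and 13 lower of 42 (0 and 14 adjusted over the list alone), median log2 -0.35, adjusted p = 0.00157 (0.836 with estimated correlation). Unfolded protein response genes had 7 higher and 0 lower of 20 (9 and 0 adjusted over the list alone), median log2 0.25, adjusted p = 0.0173 (0.808 with estimated correlation). At 48 h the stress response list had 16 higher and 2 lower of 28 (17 and 2 adjusted over the list alone), median log2 0.56, adjusted p = 0.00844 (0.817 with estimated correlation), with asparagine synthetase, ASNS, at log2 1.5 ± 0.27. NF-kB and cytokine genes then had 14 higher and 2 lower of 24 (15 and 2 adjusted over the list alone), median log2 0.89, adjusted p = 0.0199 (0.817 with estimated correlation), with CCL2 at log2 9.56 ± 0.75. At 96 h, G2/M genes had 1 higher and 26 lower of 52 (2 and 28 adjusted over the list alone), median log2 -0.40, adjusted p = 0.00431 (0.846 with estimated correlation). Interferon genes had 1 higher and 13 lower of 29, median log2 -0.55, adjusted p = 0.00361 (0.808 with estimated correlation), with OAS3 at log2 -2.36 ± 0.16. Cholesterol synthesis had 0 higher and 13 lower of 23 (0 and 15 adjusted over the list alone), median log2 -0.56, adjusted p = 0.00834 (0.83 with estimated correlation), with INSIG1, a sterol sensor, at log2 -2.23 ± 0.31. Epithelial genes had 4 higher and 11 lower of 20 (4 and 12 adjusted over the list alone), median log2 -1.71, adjusted p = 0.0199 (0.808 with estimated correlation), with ELF3, an epithelial transcription factor, at log2 -6.87 ± 0.65. Matrix genes had 8 higher and 20 lower of 36 (8 and 21 adjusted over the list alone), median log2 -0.78, adjusted p = 0.00844 (0.808 with estimated correlation), with COL7A1 at log2 -4.30 ± 0.21. Other lists that passed were G1 cyclins and ribosome biogenesis (lower at 24 and 48 h), glycolysis (higher at 24 h), ribosomal proteins (lower) and the unfolded protein response (higher) at 48 h, and TGF-beta genes (lower at 96 h).

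**Figure D3:**
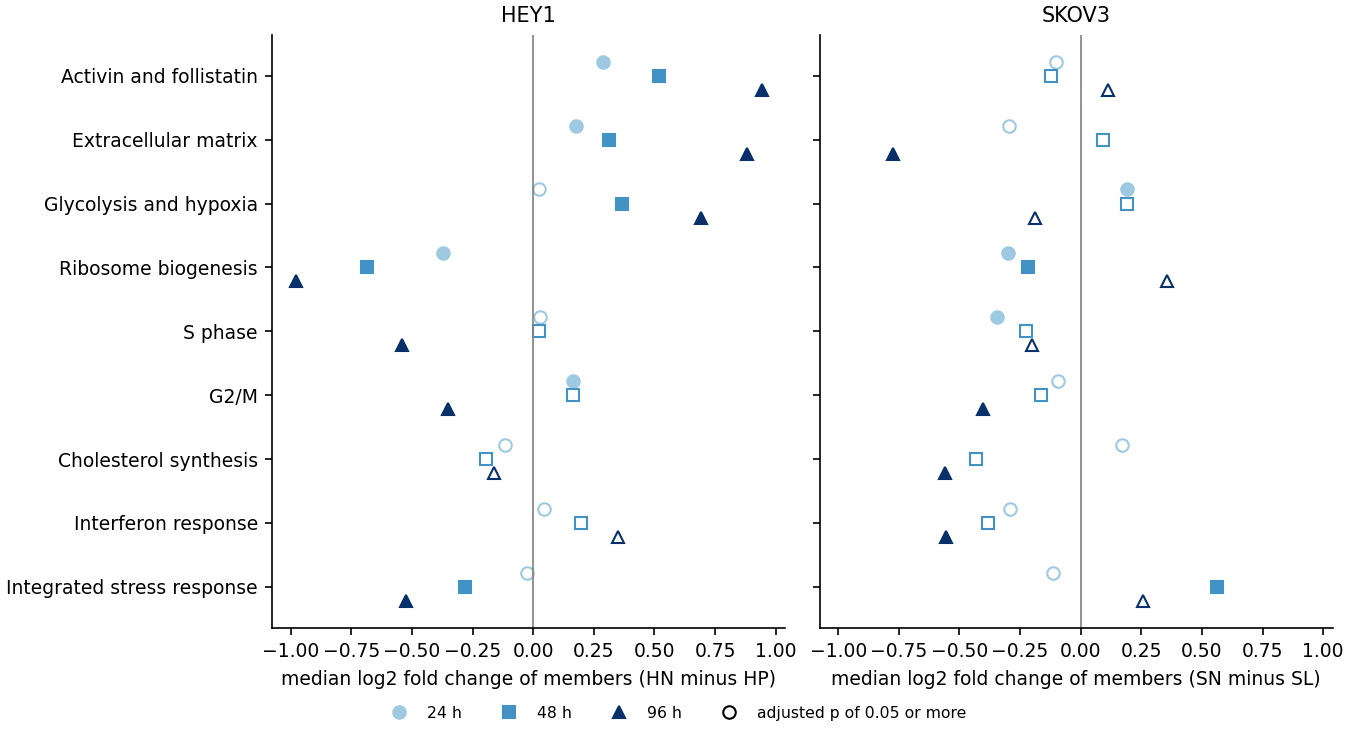
Median log2 fold change of the members of 9 gene lists at 24, 48 and 96 h, HN minus HP in HEY1 and SN minus SL in SKOV3. Filled markers passed the camera test with its preset correlation, and none passed with an estimated correlation.

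Members of the activin and BMP branch, where follistatin acts, changed in both lines. In HEY1 the list had 20 higher and 6 lower of 30 (21 and 6 adjusted over the list alone), median log2 0.62, adjusted p = 0.00834 (0.672 with estimated correlation). The activin A subunit INHBA (log2 1.79 ± 0.10), the follistatin relative FSTL3 (log2 1.96 ± 0.06) and the BMP antagonist GREM1 (log2 4.78 ± 0.18) were higher in HN. So were the BMP targets ID1 (log2 1.52 ± 0.10) and SMAD6 (log2 2.44 ± 0.16), while GDF15 was lower (log2 -1.54 ± 0.10) and SMAD7 did not pass (log2 -0.18 ± 0.13, adjusted p = 0.257). SKOV3 had 8 higher and 13 lower of 32 (10 and 13 adjusted over the list alone), median log2 -0.07, adjusted p = 0.521. INHBA was higher in SN (log2 5.54 ± 0.40), and ID1 (log2 -2.09 ± 0.13), SMAD6 (log2 -1.43 ± 0.13) and SMAD7 (log2 -1.50 ± 0.10) were lower. The difference between lines passed for SMAD7 as well, at log2 -1.32 ± 0.17 for the SN minus SL effect less the HN minus HP effect. Here FSTL3 had log2 -0.24 ± 0.08, adjusted p = 0.0118, and FSTL1 did not pass (log2 0.10 ± 0.06, adjusted p = 0.179).

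Other members of the NFAT family changed as well. NFATC1 was higher in HN (log2 5.43 ± 0.50) and in SN (log2 1.19 ± 0.11). NFATC2 was lower in HN (log2 -1.87 ± 0.12) and higher in SN (log2 0.55 ± 0.22, adjusted p = 0.0359). NFAT5, the salt-responsive member, did not pass in either (log2 0.02 ± 0.08, adjusted p = 0.87 and log2 0.11 ± 0.11, adjusted p = 0.435). PTGS2, the inducible prostaglandin synthase (log2 1.63 ± 0.50, adjusted p = 0.00701 in HEY1, log2 1.96 ± 0.51, adjusted p = 0.00275 in SKOV3), and the chemokine IL8 (log2 1.83 ± 0.15 and log2 1.75 ± 0.57, adjusted p = 0.0141) were higher in both. The whole list had 12 higher and 4 lower of 21 (12 and 5 adjusted over the list alone), median log2 0.18, adjusted p = 0.144 in HEY1 and 12 higher and 6 lower of 22, median log2 0.35, adjusted p = 0.266 in SKOV3.

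Some of the largest arm differences had the same direction in both lines. ANO1 (log2 8.23 ± 0.36 in SKOV3), COL3A1 (log2 8.83 ± 0.60) and IL33 (log2 8.94 ± 0.39) stood higher in SN as they did in HN, beside CHRNA6, POSTN, LCK, CNN1, RUFY4 and FST. FGF5 (log2 -2.90 ± 0.18) and the protease ADAMTS1 (log2 -3.16 ± 0.17) were lower in SN as in HN (log2 -2.83 ± 0.09). ANO1, COL3A1, IL33, FGF5 and ADAMTS1 were chosen here after their values were seen. Of 13898 genes tested in both lines, 5174 passed in both, and 3802 of these (73.5%) had the same printed direction. Higher in both were 2105 genes where 1232.7 would be expected from the totals (Fisher's exact test, p = 6.42e-263), and lower in both were 1697 (1123.6 expected, p = 1.71e-121). With changes of at least 2-fold in both, 396 were higher in both (58.9 expected, p = 8.4e-255 by Fisher's exact test) and 206 lower in both (37.5 expected, p = 1.53e-101). Opposite ways went 66 genes higher in HN and lower in SN (58.6 expected, p = 0.294 by the same exact test) and 43 the reverse (37.8 expected, p = 0.346). Across genes the mean effects had a Pearson correlation of 0.473 and a Spearman correlation of 0.353, and genes are not independent replicates.

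**Figure D4:**
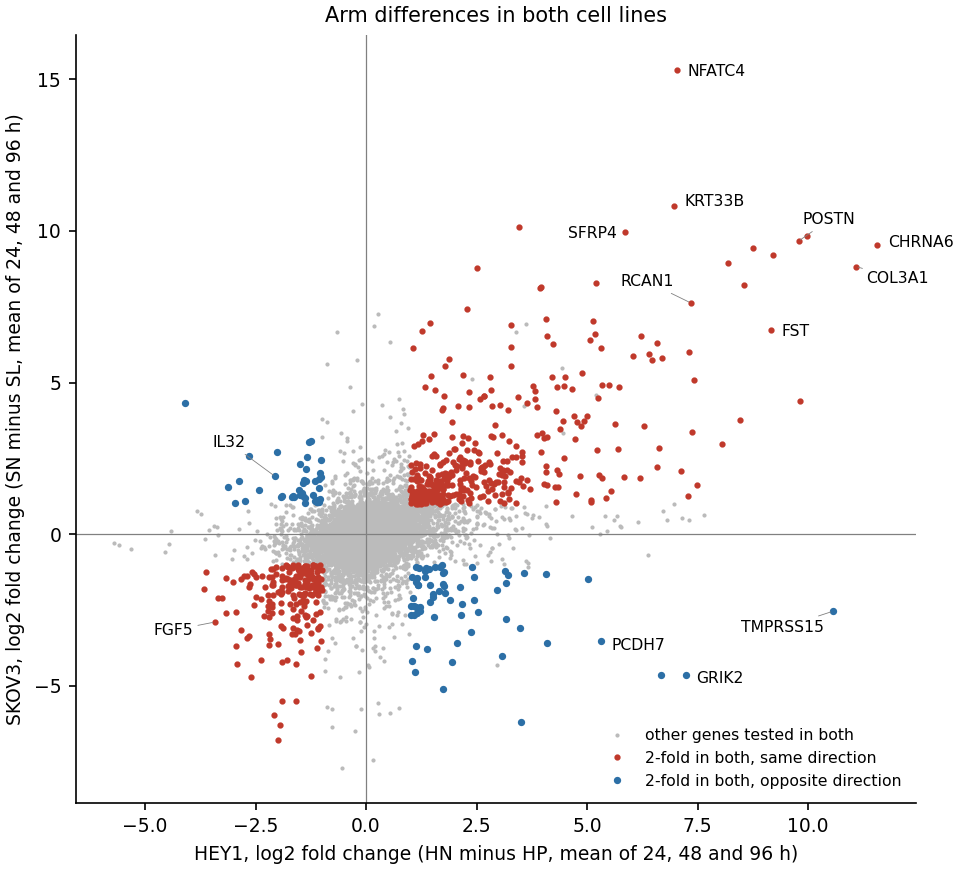
Mean log2 fold change of each gene in HEY1 (HN minus HP) against SKOV3 (SN minus SL), for the 13898 genes tested in both lines. Fitted values of genes with no counts in an arm depend on the prior count.

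Some genes went opposite ways in the 2 lines when read as HN minus HP and SN minus SL. ID1 (log2 -3.60 ± 0.18 for the SKOV3 minus the HEY1 effect), SMAD6 (log2 -3.86 ± 0.21), MMP2 (log2 -5.16 ± 0.24) and TGFB2 (log2 -4.37 ± 0.14) were higher in HN and lower in SN. IL32, a pro-inflammatory cytokine (log2 3.97 ± 0.26), went the other way. TMPRSS15 (log2 -13.13 ± 0.26), the glutamate receptor gene GRIK2 (log2 -11.92 ± 0.68) and the protocadherin PCDH7 (log2 -8.84 ± 0.24) had the largest negative differences, and FOXS1 (log2 -8.72 ± 1.15) followed. RP11-245M24.1 (log2 8.44 ± 0.52), SNCAIP (log2 6.68 ± 0.43) and MYCT1 (log2 6.62 ± 2.24, adjusted p = 0.0162) had the largest positive ones with NFATC4 (log2 8.28 ± 0.32). Those of TMPRSS15, GRIK2, FOXS1 and MYCT1, with groups at 0 counts, depend on the prior count. The call of MYCT1 is lost (adjusted p = 1.0) without the HP library numbered 3 at any of the times. FST had log2 -2.42 ± 0.89, adjusted p = 0.0267. MMP2, TGFB2 and IL32 were chosen after their values were seen. In this reading 7674 of 17524 genes passed.

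The planned main test between the lines followed the genotype tags, under which HP and SN carry the same construct name, so it adds the 2 printed effects. It called 9795 genes, 4245 of them at least 2-fold. Among the largest sums were those of genes higher in both HN and SN, NFATC4 (log2 22.33 ± 0.26), COL3A1 (log2 19.90 ± 0.75), CHRNA6 (at least 2300-fold in HEY1 and 1580-fold, interval 283 to 62300, in SKOV3) and RUFY4 (at least 500-fold and at least 486-fold). The most negative were BGN (log2 -8.76 ± 1.11), IGFBP1, which binds insulin-like growth factors (log2 -8.23 ± 0.45), NTNG1 (log2 -8.22 ± 0.34) and CDH6 (log2 -8.11 ± 2.35, adjusted p = 0.00377). The fitted values of IGFBP1, NTNG1 and CDH6, with groups at 0 counts, depend on the prior count. The call of CDH6 is lost (adjusted p = 1.0) without the HP library 24 h number 3, 48 h number 1 or 96 h number 2.

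Within the HP arm, several lists passed upward from 24 to 96 h, none with an estimated correlation, and in most of them the greater part of the members did not pass. Cholesterol synthesis had 15 rising and 1 falling of 23 (18 and 1 adjusted over the list alone), median log2 0.66, adjusted p = 3.49e-11 (0.312 with estimated correlation). HMGCS1, an early enzyme of the pathway, rose (log2 1.02 ± 0.14). NF-kB and cytokine genes had 7 rising and 0 falling of 24 (8 and 0 adjusted over the list alone), median log2 0.39, adjusted p = 2.17e-05 (0.312 with estimated correlation), with IL1A at log2 1.42 ± 0.19. Matrix genes had 12 rising and 1 falling of 36 (13 and 1 adjusted over the list alone), median log2 0.30, adjusted p = 0.000368 (0.401 with estimated correlation), and fibroblast markers, which share collagens with them, 7 rising and 0 falling of 10 (8 and 0 adjusted over the list alone), median log2 1.26, adjusted p = 5.03e-06 (0.312 with estimated correlation). Immediate early and mesenchymal lists also passed upward (adjusted p = 0.00393 and 0.0497). G2/M genes had 0 rising and 7 falling of 52 (0 and 12 adjusted over the list alone), median log2 -0.15, adjusted p = 0.00174 (0.543 with estimated correlation). Ribosome biogenesis genes had 0 rising and 8 falling of 36 (0 and 11 adjusted over the list alone), median log2 -0.19, adjusted p = 5.81e-05 (0.493 with estimated correlation). PDGFB, a growth factor of mesenchymal cells, rose (log2 2.76 ± 0.38), and IGFBP3 fell (log2 -2.36 ± 0.24). FCGRT (log2 2.56 ± 0.44) rose, and SAMD11 (log2 -3.23 ± 0.66, adjusted p = 0.00304) and NEBL (at least 6.42-fold, adjusted p = 0.00182) fell. SAMD11 and PDGFRA overlap NOC2L and FIP1L1, which have more counts. COL1A2 (15-fold, interval 2.69 to 592, adjusted p = 0.0343), PDGFRA (at least 4.12-fold, adjusted p = 0.0382) and KCNJ8, which fell (6.23-fold, interval 1.73 to 51.5, adjusted p = 0.0493), rest on few counts and lose their calls when single libraries are left out. In all 1753 genes passed, but 711, 1011, 1096 and 774 when the HP libraries 24 h number 1, 24 h number 3, 96 h number 2 and 96 h number 3 were left out.

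Within HN, 7172 genes changed between 24 and 96 h. Large rises were those of IL33 (log2 8.0 ± 0.29), COL3A1 (log2 7.08 ± 0.20) and PKD1L1 (log2 6.28 ± 0.24), and KRTAP2-3 (log2 -5.01 ± 0.51), KIAA1755 (log2 -4.77 ± 0.47), RP11-245M24.1 (23.1-fold, interval 7.89 to 112) and NOX4 (log2 -4.31 ± 0.50) fell most. PKD1L1 overlaps HUS1, which has more counts. G2/M genes had 1 rising and 46 falling of 52 (1 and 47 adjusted over the list alone), median log2 -0.59, adjusted p = 3.16e-12 (0.401 with estimated correlation). S phase genes had 0 rising and 35 falling of 42, median log2 -0.63, adjusted p = 3.16e-12 (0.401 with estimated correlation). CDK inhibitors and cell cycle exit genes had 21 rising and 3 falling of 35 (21 and 4 adjusted over the list alone), median log2 0.56, adjusted p = 0.00333 (0.401 with estimated correlation). CDKN1A, the CDK inhibitor p21, rose (log2 1.37 ± 0.13), as did the forkhead factor FOXO1 (log2 1.81 ± 0.11). TGF-beta genes had 14 rising and 4 falling of 20 (15 and 4 adjusted over the list alone), median log2 0.73, adjusted p = 0.0015 (0.286 with estimated correlation), with LTBP1, which stores TGF-beta in matrix, at log2 6.16 ± 0.20. Glycolysis and hypoxia genes had 28 rising and 2 falling of 33, median log2 0.91, adjusted p = 1.80e-08 (0.405 with estimated correlation). Upward also passed p53 target, cholesterol, interferon, immediate early, matrix and histone lists, and downward G1 cyclin, ribosome biogenesis, ribosomal protein and stress response lists. NFATC4 itself rose in HN (log2 1.08 ± 0.16), as did FST (log2 0.97 ± 0.11).

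Whether HN and HP changed differently over time was tested as the arm effect at 96 h minus that at 24 h. S phase genes had 0 higher and 30 lower of 42 (0 and 35 adjusted over the list alone), median log2 -0.61, adjusted p = 3.09e-12 (0.401 with estimated correlation). G2/M genes had 1 higher and 32 lower of 52 (1 and 36 adjusted over the list alone), median log2 -0.48, adjusted p = 1.45e-08 (0.401 with estimated correlation), including the mitotic kinase AURKB (log2 -0.96 ± 0.15). Ribosome biogenesis had 0 higher and 27 lower of 36 (0 and 31 adjusted over the list alone), median log2 -0.64, adjusted p = 8.04e-10 (0.401 with estimated correlation). Glycolysis had 21 higher and 1 lower of 33 (24 and 1 adjusted over the list alone), median log2 0.58, adjusted p = 3.26e-07 (0.458 with estimated correlation). Targets of p53 had 12 higher and 0 lower of 25, median log2 0.26, adjusted p = 0.0102 (0.401 with estimated correlation). Histones had 9 higher and 0 lower of 14, median log2 1.10, adjusted p = 0.000454 (0.143 with estimated correlation). CDK inhibitor, TGF-beta and matrix lists also passed upward, and G1 cyclin, ribosomal protein, respiratory chain and stress response lists downward. Of single genes, NOX4 (log2 -5.14 ± 0.57) was among the largest, as was GRIK2 (adjusted p = 0.0173), with 2 and 0 counts in HP at 24 and 96 h, and FST did not pass (log2 -0.14 ± 0.30, adjusted p = 0.771). The call of GRIK2 is lost without the HP 24 h library number 1, because a group is then left without counts. By this test 4354 genes passed, 2178 with a more positive and 2176 with a more negative effect at 96 h.

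In SKOV3 most G2/M genes fell with time in both arms, and cholesterol, interferon and epithelial lists passed upward in SL. SL had 0 rising and 49 falling of 52, median log2 -0.72, adjusted p = 1.80e-15 (0.429 with estimated correlation) for G2/M genes and 0 rising and 28 falling of 36 (0 and 32 adjusted over the list alone), median log2 -0.75, adjusted p = 1.05e-12 (0.458 with estimated correlation) for ribosome biogenesis. Cholesterol synthesis had 16 rising and 0 falling of 23 (17 and 0 adjusted over the list alone), median log2 0.93, adjusted p = 5.24e-09 (0.405 with estimated correlation). Interferon genes had 12 rising and 0 falling of 29 (16 and 0 adjusted over the list alone), median log2 0.58, adjusted p = 5.66e-06 (0.401 with estimated correlation). Epithelial genes had 10 rising and 2 falling of 20 (12 and 2 adjusted over the list alone), median log2 0.79, adjusted p = 0.000168 (0.401 with estimated correlation). S phase, G1 cyclin, ribosomal protein and immediate early lists also passed downward, and glycolysis, stress response, matrix and lysosome lists upward. KRT7, a keratin of simple epithelia, rose (log2 1.84 ± 0.19), as did the interferon-induced tether BST2 (log2 3.51 ± 0.44). LIX1 (log2 5.32 ± 0.70) and CRB2, a polarity gene (log2 3.72 ± 0.76, adjusted p = 0.00203), rose, and ESM1 (97.7-fold, interval 33.4 to 474, adjusted p = 0.00307) and NAV3 (log2 -4.38 ± 0.88, adjusted p = 0.00186) fell. RPPH1, the RNA of ribonuclease P (log2 3.97 ± 1.13, adjusted p = 0.0159), turned to -0.67 (adjusted p = 0.65) without the SL 96 h library number 3, and it overlaps PARP2. NHSL2 (at least 3.73-fold, adjusted p = 0.0176), ISM1 (at least 2.38-fold, adjusted p = 0.0338) and KRT8P14 (at least 3.58-fold, adjusted p = 0.0131) each lose their call when some single libraries are left out. CRB2, ISM1 and NHSL2 overlap DENND1A, TASP1 and RGAG4, which have more counts. In SL 4023 genes passed, but 2475 without the 24 h libraries numbered 2, 2078, 1948 and 2620 without SL 24 h number 1, SL 24 h number 2 and SL 96 h number 3, and 4762 without SL 24 h number 3.

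SN had 1 rising and 49 falling of 52 (1 and 51 adjusted over the list alone), median log2 -1.09, adjusted p = 2.31e-22 (0.401 with estimated correlation) for G2/M genes. Stress response genes had 20 rising and 1 falling of 28 (23 and 1 adjusted over the list alone), median log2 0.84, adjusted p = 4.89e-08 (0.405 with estimated correlation), with PHGDH, the entry enzyme of serine synthesis, at log2 2.13 ± 0.35. Mesenchymal genes had 3 rising and 9 falling of 20 (4 and 10 adjusted over the list alone), median log2 -0.52, adjusted p = 0.0015 (0.312 with estimated correlation), and fibronectin, FN1, fell (log2 -3.67 ± 0.24). S phase, TGF-beta and ribosomal protein lists also passed downward, and lysosome genes upward. The aromatase CYP19A1 (at least 151-fold), FMOD (log2 7.81 ± 0.52), CCL2 (log2 7.09 ± 0.35) and MAMDC2 (log2 6.86 ± 0.66) rose most. KRT81, whose relative KRT86 overlaps it (log2 -7.54 ± 0.38), COL6A3 (log2 -6.09 ± 0.55), MYO7B (74.7-fold, interval 25.6 to 362) and UGT1A6, which shares exons with its gene family (at least 21.6-fold), fell most. FST rose in SN (log2 1.99 ± 0.42, adjusted p = 0.00146) and did not pass in SL (log2 -0.66 ± 1.46, adjusted p = 0.786), and the difference between these changes did not pass (log2 2.64 ± 1.56, adjusted p = 0.326). In SN 4321 genes passed, and 3316 without the 24 h libraries numbered 2.

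The SKOV3 arms differed in their change over time in cholesterol synthesis, with 0 higher and 9 lower of 23 (0 and 12 adjusted over the list alone), median log2 -0.82, adjusted p = 2.67e-06 (0.47 with estimated correlation), and in epithelial genes, with 2 higher and 8 lower of 20 (2 and 11 adjusted over the list alone), median log2 -1.02, adjusted p = 0.000737 (0.401 with estimated correlation). KRT7 had log2 -3.72 ± 0.28, and INSIG1 log2 -2.31 ± 0.44, adjusted p = 0.00161. Ribosome biogenesis had 5 higher and 0 lower of 36 (18 and 0 adjusted over the list alone), median log2 0.62, adjusted p = 3.34e-06 (0.586 with estimated correlation). The stress response had 6 higher and 0 lower of 28 (7 and 0 adjusted over the list alone), median log2 0.56, adjusted p = 0.00185 (0.601 with estimated correlation). For G2/M the list had 1 higher and 0 lower of 52 (0 and 0 adjusted over the list alone), median log2 -0.39, adjusted p = 0.00081 (0.705 with estimated correlation), and the 1 member that passed, GAS2L3, had the opposite sign (log2 0.72 ± 0.23, adjusted p = 0.0477). Mesenchymal genes had 1 higher and 7 lower of 20 (2 and 7 adjusted over the list alone), median log2 -0.58, adjusted p = 0.0318 (0.401 with estimated correlation), a call also lost with the replicate block (adjusted p = 0.0585). TGF-beta, glycolysis, interferon and matrix lists also passed downward. Of single genes, KRT81 (log2 -8.93 ± 0.47) and AMTN (log2 -4.73 or further with a floor of 3 counts in SN at 96 h, adjusted p = 0.00151) were among the largest. By this test 1665 genes passed.

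Markers of other cell types were checked because cultures can hold stray cells and cancer lines can express such genes themselves. In HEY1 the endothelial receptor TIE1 was at 328.2 ± 50.2 CPM in HN and 448.8 ± 31.3 in HP (n=9), CDH5 at 14.3 ± 5.81 and 99.8 ± 62.8, and the lysosomal protein LAPTM5 of blood cells at 35.9 ± 10.3 and 101.4 ± 13. Endothelial markers had 3 higher and 4 lower of 8, median log2 -0.08, adjusted p = 0.49. Immune markers had 1 higher and 2 lower of 3, median log2 -0.77, adjusted p = 0.337. In SKOV3 they had 1 higher and 2 lower of 6, median log2 -0.45, adjusted p = 0.641 and 1 higher and 3 lower of 5 (1 and 4 adjusted over the list alone), median log2 -0.92, adjusted p = 0.566. Fibroblast and mesothelial markers, which share collagens with the matrix list, had 5 higher and 3 lower of 10, median log2 0.40, adjusted p = 0.266 in HEY1 and 4 higher and 3 lower of 11, median log2 0.52, adjusted p = 0.566 in SKOV3. COL1A1 was at 2167 ± 1430 CPM in SL and 3570 ± 1705 in SN. Fibroblast markers passed in HEY1 at 24 h, with 5 higher and 1 lower of 10, median log2 0.71, adjusted p = 0.0139 (0.808 with estimated correlation). From 24 to 96 h they passed in 3 arms. Beside HP, HN had 6 rising and 1 falling of 10, median log2 1.34, adjusted p = 0.032 (0.47 with estimated correlation). SL had 5 rising and 1 falling of 11 (6 and 2 adjusted over the list alone), median log2 1.65, adjusted p = 0.0328 (0.493 with estimated correlation). Neuronal markers had 1 higher and 2 lower of 5 (1 and 3 adjusted over the list alone), median log2 -0.80, adjusted p = 0.699 in HEY1 and 1 higher and 3 lower of 7, median log2 -0.45, adjusted p = 0.406 in SKOV3.

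The authors' deposited table gives NFATC4 a log2 fold change of 6.29, 6.61 and 6.94 at 24, 48 and 96 h in HEY1 and 11.61, 12.65 and 13.18 in SKOV3, with the same signs as here. For FST it gives 8.04, 9.21 and 8.78, and 3.21, 4.9 and 6.51. It calls 2175, 5884 and 8207 genes in HEY1, of which 2170, 5532 and 7743 are also called here by edgeR's test. In SKOV3 it calls 2787, 5338 and 6984, of which 2741, 5008 and 6412 are also called here. Every shared call has the same direction.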

Additional observations from a re-analysis of the deposited data

Results flagged for a closer look

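The tests of the first component and RCAN1 against the titles, of signs over all genes, of G2/M genes against time alone and of other splits of the libraries were chosen after the results were seen.

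NFATC4 RNA went against the titles in both lines. If single libraries had been mislabelled, some titled ILUC would lie among those titled IcNFATc4 on the first principal component. Computed without NFATC4 and RCAN1, it had 18 of 18 above every library titled IcNFATc4 of their line, which argues against this. If whole groups had exchanged names in the titles, RCAN1, an NFAT target, should be high in the same libraries. It was in 18 of 18. Such an exchange stays open, as does a construct acting otherwise than named. Each SL library had 0 to 2 NFATC4 counts, which argues against a construct expressing it there. The tags go with the counts only in SKOV3.

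Many arm differences of at least 2-fold were present at 24 h and changed little to 96 h, which might reflect a difference between the sublines apart from the construct. Such differences should not recur in the other line, so at most 60% of these genes should have the same sign there, against at least 75% if the construct were behind them. Among genes tested in the other line the share was 82.3% (95% interval 76.7 to 87.0, 186 of 226) for genes higher in SN. Genes higher in HN had 76.4% (67.9 to 83.6, 94 of 123) and genes lower in HN 75.5% (66.2 to 83.3, 80 of 106). All 3 intervals exclude 60%, although the last 2 reach below 75%. This argues against a subline difference behind all of these genes, but not behind some. Shares over all such genes took signs from pooled counts where too few for the test, and counted those without a sign as opposite. They were 72.9% (67.9 to 77.6, 248 of 340), 76.2% (68.4 to 82.9, 109 of 143) and 73.4% (65.2 to 80.5, 102 of 139). These intervals exclude 60% too. The shares for genes higher in SN and genes lower in HN lie under the 75% predicted for the construct, so over all genes these are undecided. For genes lower in SN the shares were 58.8% (51.7 to 65.6; 120 of 204) and 54.4% (162 of 298), so that for these a subline difference stays open. Genes are not independent, so the intervals may be too narrow.

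G2/M genes fell from 24 to 96 h in 3 of the arms by many members and in HP by 7. If time in culture alone were the cause, members would not pass the test of the interaction, but in HEY1 33 did, which argues against time alone. In SKOV3 1 member passed, GAS2L3, which went the opposite way (0.72, adjusted p = 0.0477). The list median fell further in SN (-1.09) than in SL (-0.72), and the list passed the interaction by camera (adjusted p = 0.00081, adjusted p = 0.705 with an estimated correlation), so that time in culture stays open there as an explanation of part or all of the fall. No biological explanation was tested.

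Differences between times were raised by the test of the arm effect at 96 h minus that at 24 h. In HEY1 4354 genes passed, and 4 of 40 splits of the libraries within times gave as many, with 6086 in the highest other. Among the largest were NEBL (8.29), GRIK2 (7.30, adjusted p = 0.0173), PKD1L1 (6.42), NOX4 (-5.14), KRTAP2-3 (-4.75), KIAA1755 (-4.52) and C6orf141 (-4.43), in log2. In SKOV3 1665 passed, and 4 of 40 splits gave as many, with 5104 in the highest other. The largest there were ISM1 (7.82, adjusted p = 0.00171), SYNPO2L (7.27, adjusted p = 0.0218), PDE4B (5.76), C6orf25 (5.68, adjusted p = 0.00123), UGT1A6 (-9.07), KRT81 (-8.93), AMTN (-7.67, adjusted p = 0.00151) and LIX1 (-7.28, adjusted p = 0.0118). With a group at 0 counts the fitted value depends on the prior count. With a floor of 3 counts there, NEBL has 5.32, GRIK2 4.16, ISM1 4.60, UGT1A6 -6.15 and AMTN -4.73. Calls lost when libraries are left out are those of GRIK2 (adjusted p = 1.0 without HP 24 h number 1), LIX1 (0.382 without SN 24 h number 2, 0.443 without both 24 h libraries numbered 2) and SYNPO2L (0.272 and 0.0583 without SL 24 h number 1 and 2, 0.0661 without both numbered 2). In both lines the splits with more genes mix the 24 h libraries and leave the 96 h arms whole or wholly exchanged. They carry the arm difference at 96 h into the interaction, a structure of the samples, so these splits do not decide whether chance can be excluded.

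The test between lines by genotype tag sums the 2 printed mean effects, and that by title is their difference. By tag 9795 genes passed (1 of 40 splits, highest other 5523). The splits mix the arms within lines, which removes the arm effects, and do not decide on chance. Among the largest sums in log2 were NFATC4 (22.33) and COL3A1 (19.90), higher in HN and SN. The most negative were BGN (-8.76), IGFBP1 (-8.23), NTNG1 (-8.22) and CDH6 (-8.11, adjusted p = 0.00377). CHRNA6 and RUFY4 have 0 counts in HP, and RUFY4 in SL, so their fitted sums (21.13 and 19.78) depend on the prior count. By title 7674 passed, with RP11-245M24.1 (8.44), NFATC4 (8.28), SNCAIP (6.68), MYCT1 (6.62, adjusted p = 0.0162), TMPRSS15 (-13.13), GRIK2 (-11.92), PCDH7 (-8.84) and FOXS1 (-8.72) the largest. The calls of CDH6 and MYCT1 are lost without single HP libraries.

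With 1 of 40 splits each, the mean effects of HEY1 (8995 genes, highest other 6868) and SKOV3 (8991, highest other 7498) argue against chance. For comparisons of 3 with 3 libraries the 10 splits are too few for a share under 0.05. The real count was the largest in each, with a highest other of 1199 against 3436 in HEY1 at 24 h, 44 against 1753 in HP from 24 to 96 h and 328 against 4025 in SKOV3 at 24 h. The highest other was 0 genes by edgeR's adjusted p at 48 and 96 h in both lines and in HN, SL and SN.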

How the results depend on the processing

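Of the tests here, those without the SKOV3 24 h libraries numbered 2 were chosen after the result was seen. With RLE size factors, no filter, the DESeq2 Wald test and the replicate block, all 15 counts of genes stayed within 1.5 times of the values reported. With the block they were 3611, 6356, 8547 and 9114 at 24, 48, 96 h and as the mean in HEY1, 4672, 6451, 7674 and 9461 in SKOV3, 1982 in HP, 7337 in HN, 4898 in SL, 5095 in SN, 4561 and 2324 for the changes over time and 10053 between lines. With only the compared groups in the fit, HEY1 at 24 h fell to 2123 genes and SKOV3 at 24 h to 2480, and the other 8 counts did not move by over 1.5 times. This fit has fewer residual degrees of freedom. Leaving out 1 library moved 7 of 288 counts. HP at 96 h against 24 h had 711, 1011, 1096 and 774 genes without HP 24 h number 1 or 3 or 96 h number 2 or 3. SL had 2078, 1948 and 2620 without 24 h number 1 or 2 or 96 h number 3. Without the 24 h libraries numbered 2, SL had 2475. The cause was not tested. Ranges over left-out libraries were 2505 to 4192, 5274 to 6520, 7632 to 8776 and 8774 to 9182 (24, 48, 96 h and mean, HEY1), 2958 to 4146, 4563 to 6212, 6061 to 7472 and 8642 to 9180 (SKOV3), 711 to 2344 (HP), 6231 to 7376 (HN), 1948 to 4762 (SL), 3223 to 4593 (SN), 3637 to 4783 and 1171 to 2110 (changes over time in HEY1 and SKOV3) and 9625 to 9984 (lines, by tag). The overlap of 1372 genes in the same direction by genotype tag becomes 109 with a 2-fold threshold and 3802 by title, by construction. With an estimated correlation 0 list tests passed by camera (16 of 256 and 22 of 192 at an unadjusted p under 0.05). With the block 54 and 68 passed, and 4 calls were lost, HP mesenchymal genes (adjusted p = 0.0694), SN TGF-beta genes (0.0665) and the SKOV3 changes over time of TGF-beta and mesenchymal genes (0.0585 each).

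Of 167 results on named genes, 155 kept direction and side of the threshold under every alternative run, and 54 of 4132 alternatives changed in the other 12. RPPH1 in SL, log2 3.97, reversed to -0.67 (adjusted p = 0.65) without SL 96 h number 3, reached 4.578 without number 2 and lost its call without SL 24 h number 1 (0.07) or 2 (0.0511). Calls lost in HP were KCNJ8 (DESeq2 0.0907, RLE 0.0501, no filter 0.0816, block 0.0596, left-out libraries up to 0.195), PDGFRA (0.0577 to 0.114 without any of the 6 libraries compared) and COL1A2 (0.106 to 0.131 without the 4 HP libraries named above). In SL they were ISM1 (0.0676 to 0.109 without 5 single libraries or the set numbered 2), NHSL2 (0.0567 to 0.0741, 3 libraries) and KRT8P14 (0.0577). For the SKOV3 change over time they were LIX1 (0.443 without the libraries numbered 2, 0.382 without SN 24 h number 2) and SYNPO2L (0.0661, 0.272 and 0.0583). GRIK2 (1.0) in the HEY1 change over time, CDH6 between lines by tag and MYCT1 by title (1.0 each) lost their calls where the library left out leaves a group with no counts, which is the alternative's own construction. For the others the cause was not tested. Depth limits genes with few counts, as most of these are, and folds where an arm has 0 counts.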

Other observations

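The paragraphs below give lists fixed before the data were examined, and no tests here were chosen after the result was seen.

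Genes tied to drug handling and to stem cell markers, both named in work on chemotherapy, went both ways. Drug transport and resistance genes had 7 higher and 14 lower of 31, median log2 -0.20, adjusted p = 0.165 in HN minus HP, and 9 higher and 11 lower of 33, median log2 -0.10, adjusted p = 0.701 in SN minus SL. The quinone reductase NQO1 was lower in both (log2 -0.70 ± 0.05 and log2 -1.42 ± 0.07), and the efflux transporter ABCC4 was lower in HN (log2 -0.88 ± 0.05). Ovarian stem cell markers had 4 higher and 4 lower of 11, median log2 0.03, adjusted p = 0.85 in HEY1 and 4 higher and 7 lower of 15, median log2 -0.39, adjusted p = 0.484 in SKOV3. ALDH1A2, an enzyme of retinoic acid synthesis, was higher in HN (log2 7.37 ± 0.32) and in SN (log2 3.37 ± 0.13), and the receptor KIT was lower in SN (log2 -6.37 ± 0.34). CD44 did not pass in HEY1 (log2 0.03 ± 0.05, adjusted p = 0.691) and was higher in SN (log2 1.31 ± 0.14), and the difference between these effects was log2 1.29 ± 0.16.

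Immediate early genes had 10 higher and 13 lower of 29 (10 and 14 adjusted over the list alone), median log2 -0.20, adjusted p = 0.567 in HEY1, with a positive mean of 0.19, and 11 higher and 11 lower of 32, median log2 -0.07, adjusted p = 0.974 in SKOV3. From 24 to 96 h the list passed upward in HP (adjusted p = 0.00393) and HN (0.0391) and downward in SL (0.0374), none with an estimated correlation. The nuclear receptor NR4A3 was higher in HN (log2 7.29 ± 0.21). Lysosome and autophagy genes had 13 higher and 6 lower of 33, median log2 0.09, adjusted p = 0.406 in HEY1 and 12 higher and 6 lower of 33, median log2 0.11, adjusted p = 0.268 in SKOV3, and at 48 h in SKOV3 11 higher and 1 lower of 33, median log2 0.21, adjusted p = 0.0199 (0.817 with estimated correlation). Over time they passed upward in SL (adjusted p = 0.00037) and SN (0.00138). TPP1, a lysosomal peptidase, was higher in HN (log2 1.40 ± 0.10). WNT targets had 5 higher and 5 lower of 13, median log2 0.01, adjusted p = 0.913 in HEY1, with a mean of 0.60 where the test pointed down, and 6 higher and 4 lower of 14, median log2 0.29, adjusted p = 0.641 in SKOV3. The WNT antagonist DKK1 was lower in HN (log2 -1.91 ± 0.07) and SN (log2 -5.51 ± 0.11), and DKK3 higher in both (log2 3.72 ± 0.08 and log2 1.5 ± 0.11). YAP targets had 7 higher and 10 lower of 21 (8 and 10 adjusted over the list alone), median log2 -0.20, adjusted p = 0.774 in HEY1 and 7 higher and 11 lower of 21, median log2 -0.18, adjusted p = 0.269 in SKOV3, with CTGF lower in HN (log2 -1.92 ± 0.14).

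Same-numbered libraries of different groups (arm or time) had a mean correlation of 0.053 in HEY1 and 0.101 in SKOV3 between their deviations from group means. Averaged over all other groups, the own number matched best for 16 of 18 and 14 of 18 libraries. Between the arms at the same time, HEY1 24 h number 2 and 96 h number 1 and SKOV3 48 h number 1 matched other numbers better.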
